A study of Homo sapiens and Mus musculus with 19 samples.

How the data were processed

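The 19 libraries hold tags at CCGG sites from mouse cerebellum at 32 weeks (2) and P21 (3), from 1000 cells of the human lines H1ES (2) and HepG2 (2), and from single cells of H1ES (5) and HepG2 (5). In the assay, as the labels describe it, HpaII cuts unmethylated sites, which receive a U-tag. A digest with MspI and NlaIII and a later one with MspI give the H-tag of hydroxymethylated sites and the M-tag of methylated sites, with a glucosylation step between. Per the submitters' processing notes, UMI-tools 0.5.4, cutadapt 1.5 and Bowtie2 2.3.4.1 were used. The role of each and the rule for counting tags are not stated.

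Each deposited table lists CCGG sites with 3 values in the unit fraction and 1 in counts. The deposited fraction values are the shares of unmethylated, methylated and hydroxymethylated tags at a site, and they sum to 1. The deposited counts are the number of tags of the 3 kinds at that site. The tables have no header. The unmethylated fraction was told from the values, since only 1 of the 3 was higher at sites crowded with CCGG than at isolated ones in every group. Of the other 2, the far larger was taken as 5mC, because 5mC is known to exceed 5hmC in mammalian DNA, and every 5hmC result rests on this. The labels place the H-tag before glucosylation, and how this order sets 5hmC apart from 5mC is not stated. Fraction times count was a whole number within 0.00358 at every site, so the tags of each kind were recovered by multiplication. The notes list hg38 for all samples, mouse included. The mouse positions cannot be hg38, and the mouse build is not stated.

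Human sites were joined to the protein-coding genes of the RefSeq table for GRCh38.p14. That table gives no strand, so the promoter planned before the data were examined could not be placed. Instead, the gene end with more CCGG sites was taken with 1000 bp on each side, and both ends were pooled on a tie. Gene bodies were trimmed by 1000 bp at both ends. No mouse annotation was analysed here. The mouse tests were therefore run on bins of 100000 bp, as planned for that case, and the mouse gene lists were not run. A gene or bin needed at least 20 tags in every library of a comparison, and only autosomes were tested.

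For each gene or bin, the tags of a mark were tested against the other kinds with edgeR 4.0.16 (quasi-likelihood, 1 term per library, Benjamini-Hochberg, threshold 0.05), in R 4.3.3. The effect is the log2 odds of the mark. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on logit shares with a pseudocount of 0.5. The tests were also run on simulated data made from libraries of these groups with 100 features changed 2-fold and 100 changed 4-fold in odds. At 2-fold, edgeR recovered 57% of mouse bins for 5hmC, 87% for 5mC and 75% for the unmethylated share. In the human data it recovered 20% of gene bodies for 5mC, 5% of gene ends and 0% of gene bodies for 5hmC. At 4-fold, it recovered 89% of mouse bins for 5hmC, 98% for 5mC and 99% for the unmethylated share. In the human data it recovered 53% of gene bodies for 5mC, 40% of gene ends and 5% of gene bodies for 5hmC. The false calls numbered 8, 9 and 12 in the mouse tests and 0 in the human ones. Unchanged features had 1 share in all simulated libraries, with no library-wide shift, whereas the real libraries differed genome-wide. These figures therefore do not give the error rates of the real comparisons.

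Genome-wide shares pooled all autosomal tags and were compared by exact permutation tests, two-sided (Python 3.11.15, SciPy 1.17.1). Single cells were not tested, because each library is 1 cell and no culture is named. Their shares carry exact Clopper-Pearson intervals at 95%. Intervals and limits cover counting error only, and a share of 0 is given with the limit of 3 counts over the total. For agreement with the 1000-cell libraries, sites were used where both libraries of a line held at least 5 tags and at least 80% of 1 kind. Chromosome dosage is the share of a chromosome in the autosomal tags over its mean in the H1ES 1000-cell libraries, scaled to a median of 1 over chromosomes. Figures were drawn with matplotlib 3.10.9.

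Genes were named by a rule fixed before the data were examined. It takes, among called genes whose groups do not overlap and with a mean of at least 100 tags, the 8 with the largest rise and the 8 with the largest fall in percentage points, then up to 4 members of each list with the smallest p. For bins it takes the 5 with the largest rise and the 5 with the largest fall. POU5F1, NANOG, ALB and AFP are given in any case. Other names are marked as chosen after their values were seen. The results of 3 genes are not reported here. Alternatives covered the tag minimum, DESeq2 1.42.0, limma on logit shares, odds relative to those of each library, 1 other kind of tag as the reference, chromosome X, a block for the replicate number, and each replicate left out. The odds of each library were taken over the features tested, so at gene ends they are those of the tested ends and not of the genome.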

Results

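The samples were mouse cerebellum at P21 (3 libraries) and 32 weeks (2 libraries), and the human lines H1ES, an embryonic stem cell line, and HepG2, from a hepatocellular carcinoma. Each line had 2 libraries of 1000 cells and 5 of single cells. At every CCGG site the assay counted tags from unmethylated, 5-methylated (5mC) and 5-hydroxymethylated (5hmC) DNA. The mouse libraries held 17406896 to 25952928 tags, with a tag at 63.9% to 65.5% of 1630178 sites. The 1000-cell libraries held 4911898 to 6644517 tags, with a tag at 51.6% to 53.7% of 2317745 sites. Single H1ES cells held 757767 to 1543724 tags. HepG2 cells 1, 2 and 4 held 526207 to 611318, and HepG2 cells 3 and 5 held 2455908 and 2434482.

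The labels do not say whether replicates came from separate animals or cultures. The p-values therefore measure only the spread between libraries, which may be technical.

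**Figure D1:**
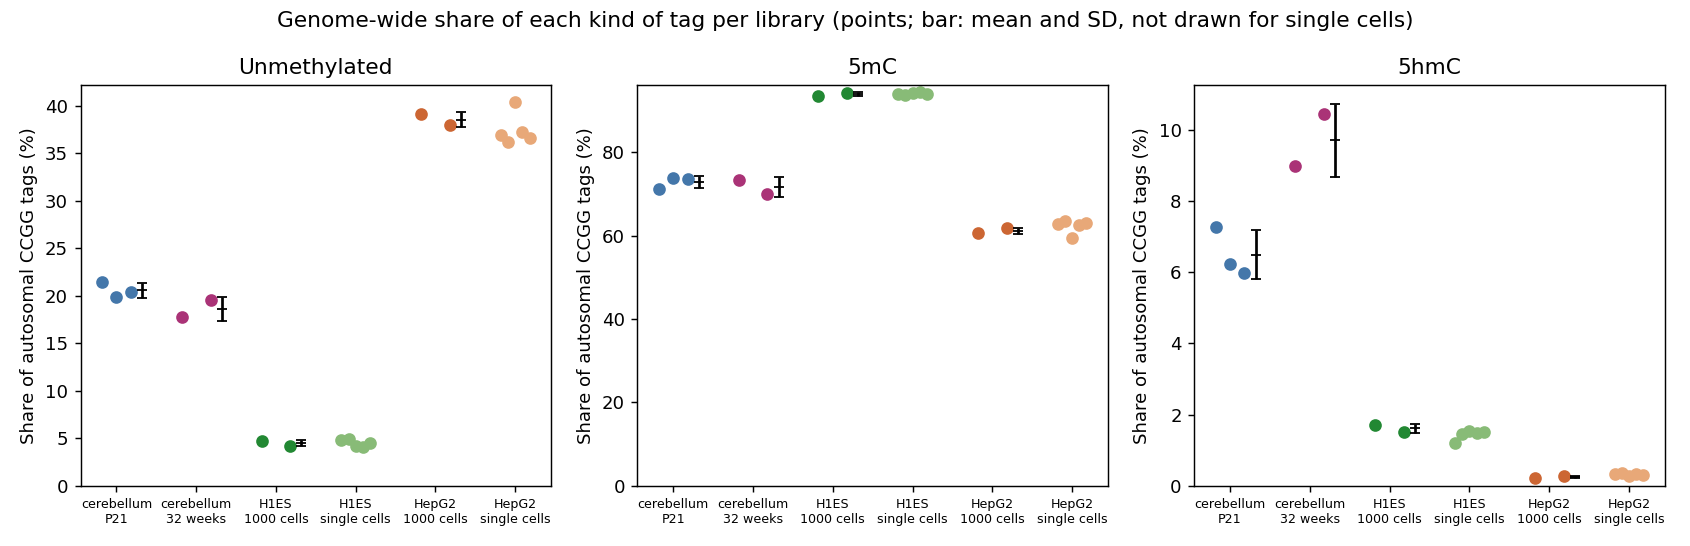
Share of autosomal CCGG tags (%) that were unmethylated, 5mC or 5hmC, 1 point per library in 6 groups, with the mean and SD of each group but the single cells beside its points. The 5hmC share lay at 8.98% and 10.4% in the 32-week cerebellum and between 5.97% and 7.27% at P21, and the mean unmethylated share was 38.6% in HepG2 and 4.49% in H1ES libraries of 1000 cells.

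The first question was how the cerebellum differed between P21, in the weeks when its circuits mature, and 32 weeks, in adulthood. The 5hmC share of autosomal tags was 9.70% ± 1.02 (SD, n = 2) at 32 weeks and 6.49% ± 0.686 (SD, n = 3) at P21. The difference of 3.22 percentage points was larger than the pooled SD of 0.872. Both 32-week libraries lay above all P21 libraries, with an exact permutation p of 0.1, which is the smallest that 10 splits allow. The 5mC share was 71.7% ± 2.297 at 32 weeks and 72.9% ± 1.44 at P21, and the unmethylated share was 18.6% ± 1.27 and 20.6% ± 0.818. Of all modified tags, 11.9% ± 1.45 carried 5hmC at 32 weeks and 8.17% ± 0.941 at P21.

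Regions of the cerebellar genome with more 5hmC at P21 gained more of it. Bins were ranked by 5hmC in P21 replicate 3, and split into 4 classes of equal size, in which the other libraries were compared. In class 1, the lowest, the mean was 4.197% at 32 weeks and 3.22% at P21, a gain of 0.979 points, and in class 4 the gain was 4.88 points. The ratio of the ages was 1.304 in class 1 and 1.502 in class 4. In class 1 the libraries nearly met, with 3.68% and 4.72% at 32 weeks and 3.63% and 2.81% at P21. In class 4 they held 13.4% and 15.8% at 32 weeks and 10.4% and 9.07% at P21. By CCGG density, isolated sites carried 9.85% at 32 weeks and 6.60% at P21, while sites with at least 10 CCGG sites within 500 bp, as in CpG islands, carried 0.968% and 0.624%. Of these crowded sites only 11.4% and 12.2% held a tag, against 81.5% and 82.7% of isolated sites.

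**Figure D2:**
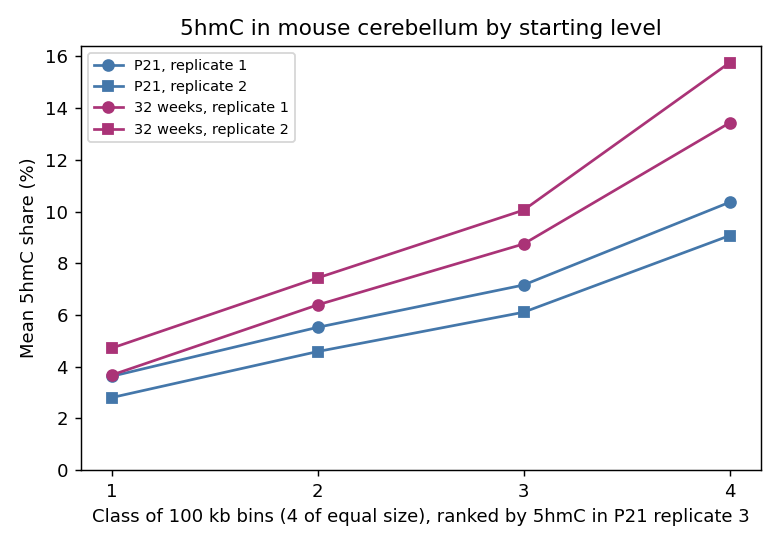
Mean 5hmC share (%) of 100 kb bins of the mouse genome, in 4 classes ranked by the 5hmC of P21 replicate 3, with 1 line for each of the other 4 cerebellum libraries. The 32-week mean exceeded the P21 mean by 0.979 points in class 1 and by 4.88 points in class 4.

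Among 23950 bins, 5hmC rose in 10674 and fell in 1 (edgeR, adjusted p under 0.05), with a median log2 odds of 0.59. Relative to each library's genome-wide odds, which removes that shift, 513 bins rose and 181 fell. The largest rise was on chromosome 12 from 77300001 to 77400000, where 36.7% ± 6.95 of tags were 5hmC at 32 weeks and 15.9% ± 1.32 at P21, a call lost against unmethylated tags alone (adjusted p = 0.555). Chromosome 17 from 90200001 to 90300000 rose from 15.6% ± 2.29 to 34.8% ± 7.51, and chromosome 15 from 41500001 to 41600000 from 11.6% ± 3.38 to 30.5% ± 2.54. Chromosome 3 rose from 114900001 to 115000000 (13.7% ± 3.83 to 32.4% ± 5.71) and from 156600001 to 156700000 (14.9% ± 1.75 to 33.2% ± 3.23). Relative to the library-wide shift, chosen after their values were seen, the largest rise was on chromosome 15 from 71600001 (5.17% ± 0.567 to 21.199% ± 3.04, relative log2 odds 1.67, adjusted p = 0.000210). The largest fall was on chromosome 13 from 119000001 (3.70% ± 1.20 to 1.58% ± 0.147, relative log2 odds -1.87, adjusted p = 0.0200), which was not called without that correction (adjusted p = 0.0655). The count fell to 3310 without 32-week replicate 2, to 5966 without P21 replicate 2, to 6693 without P21 replicate 3, and to 18 with a block for the replicate number. P21 replicates 1 and 3 held 46442 and 56341 tags on chromosome Y, against 2039 or fewer in the other libraries, and 3663 bins were called with that class as a term, a fit whose age effect rests on P21 replicate 2 alone at that age. The labels do not give the sex of the animals, and age is partly confounded with this class, since both 32-week libraries were low in these tags.

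For 5mC, 18 bins rose and 945 fell with age, and relative to each library's odds 1213 rose and 2012 fell. The count of 5mC calls was 372 with DESeq2 and 1 with a block for the replicate number. Against unmethylated tags alone the direction turned, with 1135 bins that rose and 194 that fell (median log2 odds 0.0987, against -0.0986 when 5hmC tags are counted in), so no direction of 5mC with age is settled. The largest fall was on chromosome 6 from 31100001 to 31200000, with 41.7% ± 3.37 at 32 weeks and 65.2% ± 0.657 at P21. The largest rise was on chromosome 9 from 56700001 to 56800000, with 60.4% ± 1.33 and 50.1% ± 2.22, a call lost without P21 replicate 3 (adjusted p = 0.183) and with the class of chromosome Y tags as a term (0.526). The unmethylated share fell in 2676 bins and rose in 79, with a median log2 odds of -0.15, and relative to each library's odds 846 rose and 1473 fell. Against 5mC alone 194 rose and 1135 fell, which is the fit of 5mC against unmethylated tags read in reverse and not a separate test. Chromosome 15 from 59000001 to 59100000 was 23.1% ± 1.23 unmethylated at 32 weeks and 39.8% ± 1.81 at P21, and chromosome 15 from 25600001 to 25700000 was 18.04% ± 1.27 and 34.2% ± 0.893. With the class of chromosome Y tags as a term, 155 bins were called for 5mC and 443 for the unmethylated share, and in the 3 libraries low in those tags 15 and 65. With 1 library left out, the 5mC count ranged from 83 (without 32-week replicate 2) to 1850 (without 32-week replicate 1). It was 1539, 278 and 222 without P21 replicates 1, 2 and 3, and the unmethylated count was 1187 without 32-week replicate 1 and 1595 and 1250 without P21 replicates 1 and 3.

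The labels set H1ES beside HepG2, so the next question was how the modifications of a stem cell line and a liver cancer line differed. In the 1000-cell libraries 38.6% ± 0.804 (SD, n = 2) of HepG2 tags and 4.49% ± 0.349 (SD, n = 2) of H1ES tags were unmethylated. The 5mC share was 61.2% ± 0.764 in HepG2 and 93.9% ± 0.470 in H1ES. The 5hmC share was 0.249% ± 0.040 in HepG2 and 1.61% ± 0.122 in H1ES. The unmethylated share differed by 34.1 points against a pooled SD of 0.619, with an exact permutation p of 0.333, the smallest that 6 splits allow. The gap was widest at isolated sites. Isolated sites were 42.8% ± 0.758 unmethylated in HepG2 and 1.65% ± 0.093 in H1ES, and sites with at least 10 CCGG sites within 500 bp were 60.6% and 57.0% unmethylated. Of these crowded sites only 8.21% in HepG2 and 8.34% in H1ES held a tag, against 71.3% and 71.2% of isolated sites. Crowded sites were thus little measured, and the genome-wide shares weigh isolated sites more.

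HepG2 had less 5mC than H1ES in long blocks. Among 26772 autosomal bins of 100 kb, the median 5mC was 48.2% and 49.4% in the HepG2 libraries and 96.4% and 96.7% in those of H1ES. Under 50% 5mC lay 13833 and 13506 bins in HepG2 and 19 and 21 in H1ES. Bins under 50% in both HepG2 libraries formed 2720 runs, and 369 runs of at least 10 bins held 46.7% of them. The longest spanned 70 bins on chromosome 4 from 57100001 to 64100000, with a mean 5mC of 27.5% in HepG2 and 98.1% in H1ES.

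**Figure D3:**
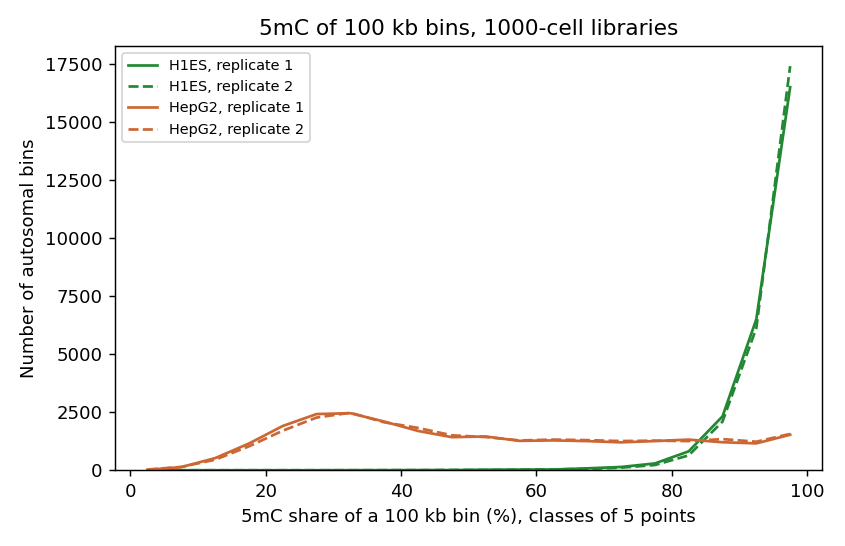
Number of autosomal 100 kb bins of the human genome by their 5mC share (%), in classes of 5 points, 1 line for each 1000-cell library. The H1ES libraries had medians of 96.4% and 96.7%, and the HepG2 libraries spread over the whole range with medians of 48.2% and 49.4%.

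Few gene bodies held more 5mC in HepG2 than in H1ES, and the 6 largest rises by the naming rule are given first. HOXA3, a homeobox gene of body patterning (chromosome 7, 27107010 to 27152583), rose to 76.2% ± 6.49 from 36.6% ± 4.60 in H1ES, with a log2 odds of 2.42 (adjusted p = 2.92e-21). PAX6, a regulator of eye and brain development, rose to 59.2% ± 2.93 from 25.4% ± 1.95, and TFAP2A, a regulator of neural crest, to 43.9% ± 7.54 from 15.8% ± 1.89. TBX4, a hindlimb regulator, rose to 87.9% ± 1.42 from 62.3% ± 6.54, RCN3, a calcium-binding protein, to 98.3% ± 0.984 from 75.1% ± 2.50, and GATA4, a regulator of heart and endoderm, to 88.3% ± 1.52 from 66.8% ± 4.72. Among the 6 largest falls, SAMSN1 went to 13.4% ± 0.217 from 97.0% ± 2.56, XKR5 to 12.04% ± 7.21 from 94.9% ± 0.432 and OR56A3, an olfactory receptor, to 16.1% ± 3.87 from 98.0% ± 0.669. ADCYAP1R1, a peptide receptor, fell to 14.9% ± 2.21 from 96.6% ± 1.35, CA8 to 17.3% ± 1.69 from 98.8% ± 0.359, and FSHR, the follicle-stimulating hormone receptor, to 17.9% ± 6.95 from 99.4% ± 0.878. Of 13438 gene bodies, 335 rose and 7377 fell (edgeR), with a median log2 odds of -1.94. Relative to each library's odds, 4705 rose and 3299 fell, with a median log2 odds of 0.87. That fit is thus not centred on the typical gene body.

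Lists of genes fixed before the data were examined were counted next, each also relative to each library's odds (in brackets). The median gene body rose by 0.87 in that fit, so a rise in brackets need not exceed that of the typical gene. Of 15 germline and cancer-testis genes measured, 14 fell and 0 rose (10 and 0), among them PIWIL1, which silences transposons in the testis (35.6% ± 1.33 against 98.5% ± 0.098), and ACTL8 (34.3% ± 4.22 against 96.5% ± 0.424). Of 12 blood genes, 11 fell and 1 rose (9 and 2), with the lymphoid regulator IKZF1 at 30.0% ± 3.09 against 95.7% ± 1.06 and the signalling gene VAV1 at 46.8% ± 0.169 against 96.6% ± 1.02. Of 15 HOX and other Polycomb targets, 5 fell and 7 rose (0 and 14). Among those that fell were PAX7 (32.7% ± 2.09 against 78.9% ± 1.03) and PAX3 (30.1% ± 2.22 against 63.9% ± 0.083), regulators of muscle and neural crest. Relative to each library's odds PAX7 was not called (edgeR, adjusted p = 0.679), and PAX3 rose by 0.87, as did the median gene body. Of 12 pluripotency genes, 8 fell and 1 rose (5 and 4), with VRTN at 41.9% ± 3.34 against 92.2% ± 3.53 and the telomerase gene TERT at 69.7% ± 4.99 against 99.0% ± 0.660. Of 14 hepatocyte genes, 8 fell and 0 rose (1 and 4), with the protease inhibitor SERPINA1 at 25.7% ± 9.04 against 94.8% ± 1.53. Of 12 liver enzymes 6 fell and 0 rose (2 and 3), and of 16 genes reported as methylated in liver cancer 11 fell and 0 rose (3 and 8). SPINT2, from the second, stood at 54.2% ± 2.79 against 98.7% ± 0.311.

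Of 8 neural genes, 3 fell and 2 rose (relative to each library's odds, 2 and 5), the falls including SYT1, of synaptic vesicles (34.8% ± 4.74 against 98.0% ± 0.659), and MAP2, of dendrites (37.1% ± 2.23 against 95.6% ± 0.490). Of 15 imprinted genes, 8 fell and 1 rose (2 and 10), with KCNQ1 at 49.0% ± 1.06 against 95.5% ± 0.025 and SNRPN at 37.4% ± 0.698 against 94.6% ± 2.05. Of 15 genes of the DNA modification machinery, 6 fell and 1 rose (0 and 10). The methyltransferase DNMT3A was at 80.7% ± 0.987 against 87.3% ± 0.292, and relative to each library's odds it rose by 2.18. Of 8 housekeeping genes, 2 fell and 0 rose (0 and 1). Against other genes, camera called the Polycomb targets higher (adjusted p = 9.30e-06), the germline genes lower (0.00374) and the machinery higher (0.00485). None held with an estimated correlation (adjusted p = 0.376, 0.376 and 0.402, in that order). Adjusted over the list alone, the counts were the same in 9 of the 11 lists, while 3 neural genes rose and 1 housekeeping gene fell. These list tests on gene bodies were chosen after the data were seen.

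**Figure D4:**
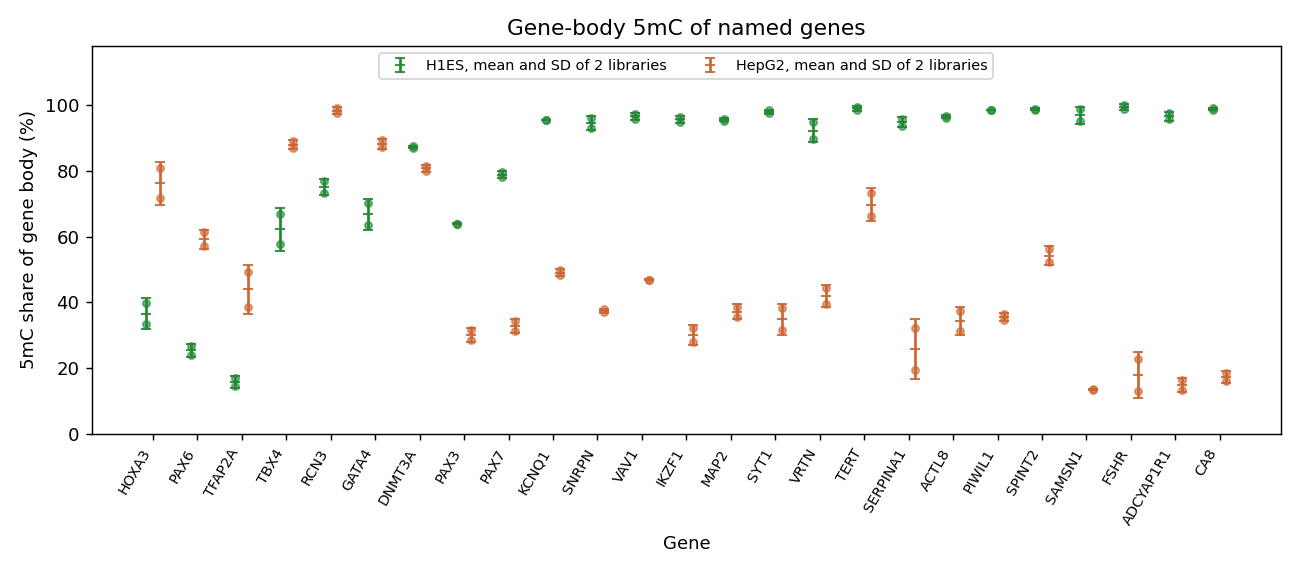
5mC share (%) of the bodies of 25 named genes in the 1000-cell libraries of H1ES and HepG2, with points for the libraries and bars for the mean and SD of 2 libraries. HOXA3, PAX6, TFAP2A, TBX4, RCN3 and GATA4 lay higher in HepG2 and the others lower, which for PAX3 and DNMT3A turned relative to each library's odds.

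At gene ends, which stand in for promoters here, the unmethylated share changed in both directions. Without a strand, the end taken may lie where transcription starts or where it stops. A change at a named gene is therefore not placed at its promoter. HNF4A, a master regulator of hepatocytes (chromosome 20, 44355699 to 44434596), was 93.0% ± 3.13 unmethylated in HepG2 and 1.72% ± 2.44 in H1ES (adjusted p = 2.69e-28). APOC3, an apolipoprotein of the liver, was 29.0% ± 7.56 unmethylated in HepG2, with 0% in H1ES. MYLK2, a muscle kinase and the only gene named for its rise, went to 42.8% ± 0.475 from 0.766% ± 0.276. The share fell at L1TD1, a pluripotency gene (25.6% ± 9.03 against 81.3% ± 1.85), and at HOXC10 (22.04% ± 11.9 against 86.9% ± 6.06). HOXA3 was at 32.8% ± 3.32 against 62.8% ± 1.81, a call lost without H1ES replicate 2 (adjusted p = 0.0624) or HepG2 replicate 1 (0.0555). CCND2, a cyclin reported as methylated in liver cancer, did not pass (76.9% ± 14.5 against 94.2% ± 8.16). It was lower relative to each library's odds at the tested ends (edgeR, log2 odds -3.27, adjusted p = 0.00425). Outside the rule and chosen after their values were seen, SLC4A1, the anion exchanger of red cells, was 96.4% ± 5.05 unmethylated in HepG2 and 0% in H1ES, and ITIH3, made in the liver, 95.8% ± 5.89 and 0%. ACOXL fell to 2% ± 2.83 from 92.1% ± 4.04 and SIM1, of the hypothalamus, to 27.9% ± 0.918 from 92.4% ± 10.7. Of 884 gene ends with 20 tags, 393 rose and 47 fell, with a median log2 odds of 1.62. Relative to each library's odds at these ends, 265 rose and 107 fell. Genome-wide, the mean unmethylated shares were 38.6% in HepG2 and 4.49% in H1ES, and no fit of gene ends relative to those was run. The 0% in H1ES allowed up to 4.55% for APOC3, 5.45% for SLC4A1 and 4.84% for ITIH3 (3 counts of all tags).

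At 20 tags only 4 lists kept 2 or more gene ends, so a minimum of 5 tags was added after the data were seen. Of 16 hepatocyte genes 6 rose and 0 fell, among them APOH (89.8% ± 2.68) and the thrombin gene F2 (91.1% ± 5.12), both at 0% in H1ES. The values of 0% at this minimum allowed up to 7.895% (GDF3) to 12% (CYP2E1). Of 8 liver enzymes 4 rose and 0 fell, with CYP2E1, which oxidises ethanol, at 91.2% ± 12.5 against 0%. Of 15 pluripotency genes 3 rose and 4 fell. The Nodal inhibitor LEFTY1 was at 92.1% ± 11.2 against 0% and the growth factor GDF3 at 66.9% ± 11.4 against 0%, whereas ZFP42 was at 16.3% ± 14.7 against 83.0% ± 8.31. Of 18 genes reported as methylated in liver cancer 2 rose and 5 fell, the falls including the detoxifying enzyme GSTP1 (27.0% ± 22.4 against 79.8% ± 2.86), the Wnt antagonist SFRP1 (34.7% ± 7.49 against 87.5% ± 4.88) and the imprinted growth inhibitor CDKN1C (8.89% ± 1.11 against 80% ± 8.08). Of 12 Polycomb targets 1 rose and 4 fell, and of 12 neural genes 1 rose and 2 fell, with SOX1 at 6.67% ± 9.43 against 100%. Of 10 blood genes 4 rose, of 10 germline genes 3, with HORMAD1 at 51.9% ± 2.72 against 0%, and neither list held a fall. Of 10 imprinted genes 1 rose and 2 fell, of 14 housekeeping genes 1 rose, and of 13 machinery genes 0 changed. With HepG2 replicate 2 left out 1390 ends were called, against 3348 with all libraries, and 0 were called without H1ES replicate 1 (2685 at an unadjusted p under 0.05), without H1ES replicate 2 (3112) or without HepG2 replicate 1 (3111). The 11 genes given here in values had adjusted p between 0.0628 and 0.295 in those last 3 fits.

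At 20 tags, camera called only the Polycomb targets (2 members, HOXC10 and HOXA3, both lower; adjusted p = 0.00617), and not with an estimated correlation (adjusted p = 0.440). The other 3 lists, hepatocyte (2 of 3 higher), pluripotency (1 of 2 lower) and housekeeping (0 of 2 changed), were not called. Adjusted over the list alone, their counts were the same. At 5 tags, camera called the genes reported as methylated in liver cancer (adjusted p = 0.00371), the Polycomb targets (0.00371) and the neural genes (0.00682) lower than other genes. None held with an estimated correlation (adjusted p = 0.378, 0.378 and 0.383). Camera did not call the other lists, among them the hepatocyte genes (adjusted p = 0.226), liver enzymes (0.170), blood genes (0.603) and germline genes (0.869). Adjusted over the list alone, 1 neural gene fell, 1 blood gene also fell, 2 imprinted genes rose and no housekeeping gene changed, and the other lists had the counts given above.

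For POU5F1, the stem cell regulator also called OCT4, tags were pooled over libraries. Its gene end was unmethylated in 20 of 24 tags in H1ES 1000-cell libraries (83.3%, exact Clopper-Pearson interval 62.6% to 95.3%) and in 2 of 40 in those of HepG2 (5.00%, 0.611% to 16.9%). In single cells it was unmethylated in 2 of 5 tags in H1ES and 0 of 26 in HepG2, whose exact interval reached 13.2%. For NANOG, another stem cell regulator, the end was unmethylated in 3 of 27 tags in H1ES and 10 of 24 in HepG2. ALB and AFP, the albumin and fetal albumin genes, had 0 tags at their ends in every human library. The ALB body was methylated in 20 of 20 tags in H1ES and 17 of 21 in HepG2, and the AFP body in 14 of 14 and 15 of 17. In single cells the NANOG end was unmethylated in 0 of 10 tags in H1ES and 5 of 11 in HepG2, and the ALB body was methylated in 10 of 10 and 14 of 18. The AFP body went the other way there, with 7 of 12 tags methylated in H1ES and 15 of 15 in HepG2.

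5hmC was lower in HepG2 at every gene body called: 0 rose and 2010 fell of 13438 (edgeR), with a median log2 odds of -2.16. Relative to each library's odds 3 rose and 3 fell. The calls numbered 5573 against unmethylated tags alone and 1018 with a block for the replicate number, all of them falls. KCNH3, a potassium channel, held 6.92% ± 0.420 5hmC in H1ES, the carbonic anhydrase CA4 6.56% ± 0.246, ITM2C 6.46% ± 1.83 and KIRREL1, an adhesion gene, 5.97% ± 2.67, with 0% in HepG2, where the tags allowed up to 0.584% (KIRREL1) to 1.20% (KCNH3). DNMT3A held 4.56% ± 0.292 in H1ES and 0.271% ± 0.055 in HepG2, and the 5mC oxidase TET3 3.65% ± 0.532 and 0.537% ± 0.049. KCNQ1 held 2.01% ± 0.173 and 0.175% ± 0.016, and PAX7 3.43% ± 0.304 and 0.196% ± 0.022. Camera called 0 of 11 lists, and 0 list members were called relative to each library's odds. Fry, which tests whether a list moves one way on balance, called 8. It does not compare a list with other genes, so those 8 calls cannot be told apart from the fall over all gene bodies. The falls numbered 4 of 15 imprinted genes, 4 of 16 genes reported as methylated in liver cancer, 3 of 15 germline genes, 2 of 15 Polycomb targets, 2 of 15 machinery genes and 2 of 8 neural genes. There was 1 fall each among 12 pluripotency genes, 12 liver enzymes and 12 blood genes, and 0 among 14 hepatocyte and 8 housekeeping genes. Adjusted over the list alone, 5 Polycomb targets, 4 germline genes and 0 blood genes fell, and the other lists had the same counts. The count fell to 680 without H1ES replicate 1, 1102 without H1ES replicate 2 and 1098 without HepG2 replicate 1, and the calls of KCNH3 (adjusted p = 0.103 without H1ES replicate 1 and 0.0580 without H1ES replicate 2) and ITM2C (0.0507 without H1ES replicate 2) were lost.

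The last question was whether single cells resembled the 1000-cell libraries of their line. At 29922 sites where the lines held opposite kinds, 97.8% to 98.9% of the tags of an H1ES cell and 84.1% to 88.4% of those of a HepG2 cell went with their own line. The lowest value, in HepG2 cell 5, had an exact Clopper-Pearson interval of 83.9% to 84.3%. H1ES cells were 4.12% to 4.91% unmethylated (median 4.50%, n = 5) and HepG2 cells 36.2% to 40.4% (median 36.9%, n = 5). The 5hmC share was 1.20% to 1.53% in H1ES cells and 0.266% to 0.350% in HepG2 cells. At sites that the 1000-cell libraries read as 5mC, 97.7% to 98.2% of tags were 5mC in H1ES cells and 95.8% to 96.4% in HepG2 cells. At unmethylated sites, 86.8% to 88.5% were unmethylated in H1ES cells and 84.1% to 88.5% in HepG2 cells. The own-line share of H1ES cells thus lay near their agreement at 5mC sites, and that of HepG2 cells near their agreement at unmethylated sites. H1ES had 6155 unmethylated reference sites, so most of the 29922 sites were 5mC in that line. Of all autosomal tags of H1ES cells 93.6% to 94.4% were 5mC, so their high own-line share was largely given by that level. Agreement at unmethylated sites lay far above the genome-wide unmethylated share in both lines. At unmethylated sites the ranges of the lines overlapped. The lower own-line share of HepG2 cells does not by itself show a weaker resemblance to their line.

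HepG2 is known to carry extra copies of several chromosomes, and its tags per chromosome were compared with those of H1ES. In the 1000-cell libraries chromosome 20 held 1.93 ± 0.006 times (SD, n = 2) its share in H1ES, chromosome 16 1.57 ± 0.004, chromosome 2 1.41 ± 0.004, chromosome 17 1.35 ± 0.005, chromosome 14 1.34 ± 0.008 and chromosome 6 1.33 ± 0.003. The other autosomes lay between 0.909 and 1.06. Single HepG2 cells showed chromosome 20 at 1.84 to 1.98 and chromosome 16 at 1.51 to 1.66. In HepG2 cell 1 chromosome 14 was at 1.06, against 1.29 to 1.38 in the other 4 cells. With each site counted once, chromosome 20 stood at 1.09 in the HepG2 1000-cell libraries and at 1.205 to 1.64 in single HepG2 cells. That count cannot grow at a site that already holds a tag, so it flattens gains in deep libraries. The deep cells 3 and 5 stood at 1.205 and 1.226, and cells 1, 2 and 4 at 1.60 to 1.64.

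**Figure D5:**
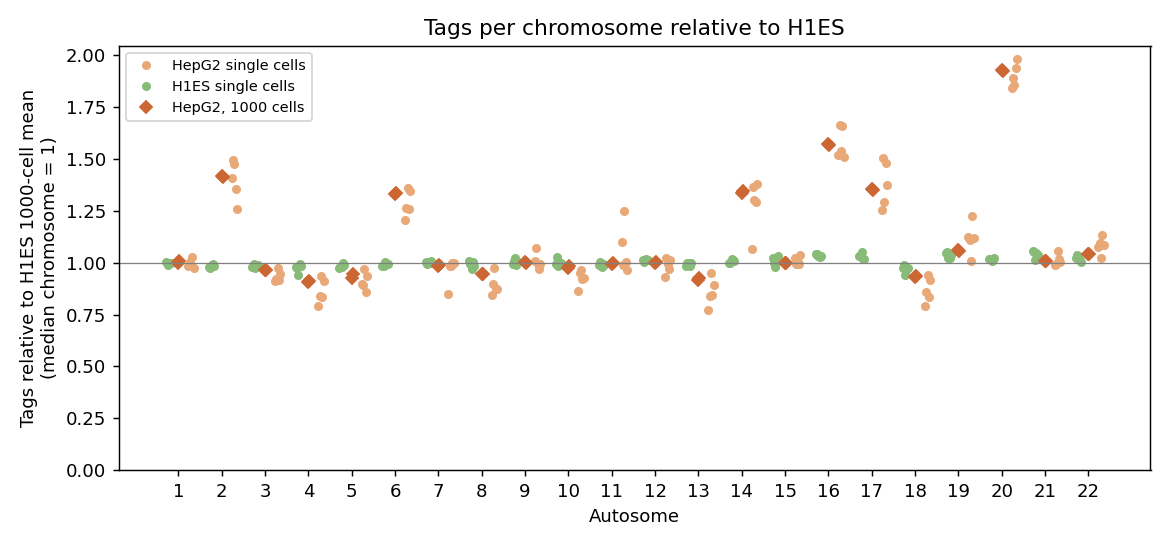
Tags on each autosome relative to the mean of the H1ES 1000-cell libraries, scaled to a median chromosome of 1, for HepG2 1000-cell libraries (diamonds, 2 per chromosome) and single cells of both lines (circles, 5 per line). In HepG2 chromosomes 2, 6, 14, 16, 17 and 20 lay between 1.33 and 1.93 in the 1000-cell libraries.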

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

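The tests of the mouse 5hmC pattern were chosen after the result was seen, and those of the 2 deep HepG2 cells before.

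In the cerebellum, 5hmC was higher at 32 weeks than at P21. One factor on the H tags of each library does not account for local differences, since 694 of 23950 bins departed from the library-wide change. Unmethylated sites read as H would raise 5hmC most where CCGG sites crowd, and there it rose by 0.344 points against 3.25 at isolated sites. What stays open is the class of P21 replicates 1 and 3, which held 46442 and 56341 tags on chromosome Y, because with it as a term the median log2 odds of 0.67 rests on 1 P21 library, and the labels give no sex. Also open are one factor on the H tags for the shared part of the rise, because the ratio of 5mC to unmethylated tags differed by 0.312 between ages with a pooled SD of 0.310 and overlapping groups, and an effect of age, which was not tested apart from it.

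HepG2 cells 3 and 5 held 4.28 times the autosomal tags of cells 1, 2 and 4. Sites with many copies were argued against, since outside sites with over 8 tags the fold was 4.18. More than 1 cell in a tube could not be excluded. At sites of intermediate methylation, pairs of tags from cells 3 and 5 disagreed in 39.6%, against 37.4% in cells 1, 2 and 4 and 46.7% in the 1000-cell libraries. That lies nearer to single cells, but the bound set beforehand asked too much. A tube with 2 cells would close only part of the gap, and cell 5 (40.8%) lay above all of cells 1, 2 and 4. The measure may also vary with depth, since H1ES cell 4, the deepest of its line, disagreed in 33.6% against 29.9% to 31.4% in the others. Over 4 tags lay at 8.49% and 8.95% of sites with a tag in cells 3 and 5, against 0.139% to 0.229% in cells 1, 2 and 4. That too cannot be told apart from their depth. No biological explanation was tested.

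Other values stood apart from the remaining 4 cells of their line by Dixon's criterion, which chance meets in about 1 in 20 groups; 66 groups were examined and 7 met it. H1ES cell 1 had the lowest 5hmC share, 1.20% against 1.45% to 1.53%. HepG2 cell 3 had the highest unmethylated share, 40.4% against 36.2% to 37.2%, and the lowest 5mC share, 59.3% against 62.4% to 63.4%. In HepG2 cell 4 the mitochondrial tags, scaled to 1e6 tags of the library, numbered 9162.2 against 5573.3 to 6190.0. HepG2 cell 5 had the highest mitochondrial 5mC share, 18.1% against 9.21% to 10.6%. In HepG2 cell 1 chromosome 7 stood at 0.849 against 0.982 to 0.999 and chromosome 14 at 1.06 against 1.29 to 1.38. Tags on the mitochondrial genome, which no comparison used, were read as 5mC in 5.87% to 18.1% across the 14 human libraries. Whether these reads were true 5mC was not tested. HepG2 cell 5, the highest, also had the lowest agreement at unmethylated sites of the single cells (84.1%).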

How the results depend on the processing

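The class of chromosome Y tags, the 3 libraries low in them, the minimum of 5 tags, both gene ends pooled, the lists on gene bodies and the 1000-cell replicates left out of the single-cell reference and the dosage were chosen after seeing the data; the cause of a change was not tested. Where an arm was left with 1 library, as P21 is outside the class, that library is assumed to vary like the others. Of 772 values of named genes and bins under alternatives, 703 stayed on their side of the threshold in the same direction, 61 lost the call, 6 gained it and 2 reversed (PAX3 0.87 and DNMT3A 2.18 log2 odds for gene-body 5mC, relative to each library's odds). Genome-wide, the mouse difference was 10.3 points against unmethylated tags alone and 2.49 to 3.94 with 1 replicate left out, and the human one 33.2 (site mean, 5 tags) and 29.8 (10 tags in every library). Mouse bins called for 5hmC numbered 694 in the relative fit, 18 with the replicate block, 3663 with the Y-tag class, 5202 in the 3 libraries and 3310 to 13587 with 1 replicate left out. For 5mC they numbered 1329 against unmethylated tags alone, where the direction turned (1135 rose and 194 fell), 372 with DESeq2, 3225 relative, 1 with the block, 155 with the class, 15 in the 3 libraries and 83 to 1850 with 1 replicate left out. For the unmethylated share they numbered 1329 against 5mC alone (194 rose and 1135 fell, the same fit read in reverse), 116 with the block, 443 with the class, 65 in the 3 libraries and 1187 to 3386 with 1 replicate left out. Human gene bodies with changed 5mC numbered 8004 relative, where the direction turned (4705 rose and 3299 fell, with a median log2 odds of 0.87). They numbered 4283 at 100 tags, where 6386 genes were left to test. Gene ends numbered 3948 at 1 tag, 3348 at 5 tags and 1580 with both ends pooled, and 100 tags left too few to run. Gene bodies with changed 5hmC numbered 6 relative, 5573 against unmethylated tags, 1018 with the block and 680 to 1557 with 1 replicate left out. Gene lists called at gene ends numbered 0 with an estimated correlation, 2 by fry, 1 to 2 with 1 replicate left out, 3 at 5 tags, and 3 and 0 on gene bodies for 5mC and 5hmC. In the HepG2 1000-cell libraries chromosome 20 stood at 1.83 without U tags, 1.09 with each site once, a count that flattens gains at this depth, and 1.89 to 1.97 with 1 replicate left out. The lowest own-line share of a cell was 85.2% at 90% of 1 kind, 84.7% at 10 tags, 89.3% with each site once and 81.8% to 84.1% with a reference replicate left out. Replicate numbers did not pair the samples (correlations of matching numbers from -0.099 to 0.016). At 4-fold odds the human 5hmC test recovered 5% of changed genes, the least among the 6 tests.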

Other observations

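The gene families and their tests in this part were chosen after the table of gene bodies was seen, and the predictions of the 2 explanations before their results.

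Families of receptors, channels and adhesion proteins had less gene-body 5mC in HepG2. Of 26 olfactory receptors all fell (24 relative to each library's odds), from a mean of 96.4% ± 3.37 (SD over genes) in H1ES to 33.4% ± 17.5, and of 71 potassium channel genes 67 fell (50), from 92.9% ± 8.54 to 44.9% ± 17.1. All 26 glutamate receptor genes fell (94.0% ± 3.97 to 35.4% ± 13.3; 23 relative to each library's odds), as did all 13 GABA receptor genes (96.4% ± 2.19 to 38.4% ± 16.4; 12) and 22 of 23 cadherins (95.4% ± 3.02 to 41.0% ± 20.7; 19). All 37 clustered protocadherins fell (85.1% ± 2.91 to 54.4% ± 11.9), but relative to each library's odds 27 rose and 3 fell. Their median log2 odds in that fit was 0.79, against 0.87 over all gene bodies. The estimated correlation between these 37 genes was 0.765, against 0.106 or less in the other families. Their calls and SD therefore do not stand for 37 independent genes. Of 32 genes of the mitochondrial ribosome 5 fell, with means of 95.7% ± 11.1 and 93.6% ± 13.01, whereas relative to each library's odds 10 rose and 0 fell. Of 30 proteasome genes 8 fell, and relative to those odds 6 rose and 2 fell. Among 13 families tested, camera called the 6 receptor, channel and adhesion families lower than other genes (adjusted p = 1.28e-08 to 0.000337), and none with an estimated correlation (adjusted p = 0.164 to 0.502). It also called the solute carriers lower (adjusted p = 0.0311; 0.260 with an estimated correlation), and the mitochondrial ribosome (0.000841; 0.217) and the proteasome (0.0443; 0.217) higher.

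For all 6 families together, a candidate explanation is that the low 5mC belongs to the region around these 196 genes. The flanks of 100 kb on each side, family genes left out, had a mean HepG2 5mC of 51.9% ± 20.7 (SD over genes) against 43.0% ± 17.5 in the bodies, within the 10 points set for this explanation. The median bin of 100 kb held 48.2% and 49.4% in the HepG2 libraries, and flanks of other genes were not measured. The test therefore cannot show that the region around these genes is lower than elsewhere. Its means and SDs also count the 37 correlated protocadherins as separate genes. A low number of CCGG sites per kb was argued against, because genes matched on it had a median of 86.2% in HepG2, against 41.2% in the families. A difference between the lines in the genes themselves stays open and was not tested.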
